A study of Mus musculus with 29 samples.

How the data were processed

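Total RNA of mouse lung, from C57BL/6 mice 6 to 8 weeks old, was extracted with TRIzol and a column kit, amplified and labelled with Cy3, and hybridised in equal amounts to Agilent whole mouse genome 4x44K arrays, per the labels' protocols. The deposited scanner files hold the intensity of each spot, made with Agilent Feature Extraction 10.7.3.1, per the file headers, while the submitters' processing notes name version 10.6. In these files the processed signal is background-subtracted and detrended within the array and is not normalized between arrays, per the file headers. The deposited series table holds log2 values, 1 per probe and array. Its columns follow the log2 of the spots' median signal without background subtraction (Spearman 0.99999 to 1.0) more closely than the processed signal (0.99169 to 0.99812), their medians lie between 8.28 and 8.30, and 28 of 29 share 1 maximum, as quantile normalization gives. Its method and centring are not given in the sources used here, and it was used only as an alternative. The arrays were scanned on 1 day on 8 slides of 2 to 4 arrays analysed here, each with more than 1 group. Samples were grouped by the genotype, treatment and time in their labels. Replicate numbers are not shared between groups, so no pairs were formed. No arrays held identical values, and arrays of 1 group correlated with r = 0.97086 to 0.99227.

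Control spots and the 0.101 to 0.908% of spots marked as outliers were left out, and no spot was saturated. Spots of a probe were averaged (245 probes had several). The log2 of the processed signal minus the array's 75th percentile was used. Probes were kept when well above background on at least 3 arrays of at least 1 group, which left 33931. Probes were named through the accession in the files, matched to a RefSeq gene table of GRCm38.p6: of 41174 probes, 24844 matched 1 gene, 0 several and 16330 none. The files' design build is mm9, so no coordinates are printed, and the table was used only for names and neighbours. Each gene was represented by its kept probe with the highest mean signal. Probes of gene families with near-identical members (Mt1 and Mt2, Serpina3, Clca3a, Klra, Nat8, olfactory and vomeronasal receptors) may share signal between members. Of the 15350 genes tested, 432 had a missing value on at least 1 array.

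One linear model with 8 group means was fitted to all 29 arrays with limma 3.58.1 (lmFit, eBayes) in R 4.3.3, so that all groups share 1 estimate of the spread. From it came 15 comparisons: dexamethasone against saline in each genotype at each time, knockout against wild type in each treatment and time and averaged over these, the difference of the dexamethasone effects between genotypes at each time and averaged, the difference of the dexamethasone effect between 8 and 4 h in each genotype, and saline at 8 against 4 h averaged over genotypes. Adjusted p-values are Benjamini-Hochberg values within a comparison, and genes with an adjusted p under 0.05 are called. A gene not well above background on any array of the lower group has a bound: the higher group's mean against the mean of, per array, the higher of the lowest signal among probes well above background and the gene's own signal.

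The test, the groups, the 30 gene lists, the rule for named genes and the alternatives named as such were chosen before the data were examined. The rule names Klf15 and Nr3c1 in every comparison, and Aass, Prodh, Mt2, Fkbp5, Per1 and Tsc22d3 in any. In dexamethasone and genotype comparisons it adds the 6 largest rises and 6 largest falls among called genes with proper symbols whose groups' arrays do not overlap. In interaction and time comparisons it adds the 10 genes with the lowest adjusted p, in each comparison up to 4 members per list with the lowest p, and genes called in the mean genotype effect within 10 Mb of Klf15. Some genes that the rule takes are not reported here. Lists were tested against all other genes with camera (preset correlation 0.01, and estimated correlation beside it) and adjusted over the 30 lists. A list's count over all genes stands beside the count with p adjusted over the list alone. Members of several lists overlap, and the lists hold markers of other tissues that lung samples could carry.

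Slide was included as a fixed block, and as a random block (consensus correlation 0.41), and comparisons were repeated within slides that held both groups. Other alternatives were quantile normalization, no filter, a filter on all arrays, the mean of a gene's probes, trend and robust variance, array weights, only the groups compared, the deposited table and leaving out each array. Background correction by normexp on the mean signal was not run, because the files used here give the median signal; it was run on the median signal (offset 50), followed by quantile normalization. That setting, median scaling, the share of probes well above background as a covariate, the dimmest kept probe of a gene, the ratio of bright to dim probe as a covariate, and fits without slide 8 or without the arrays that the scanner software marked for evaluation were chosen after seeing the data. The procedure was tested on simulated independent noise, without slide or probe differences, with 200 of 15350 genes changed. It recovered 46.3%, 83.6% and 87.9% of genes changed by 0.5, 1 and 2 log2 units for dexamethasone in wild type at 4 h, with 3 false of 148 calls. For the interaction at 4 h it recovered 20.9%, 62.7% and 92.4%, with 4 false of 121, and for the mean genotype effect 79.1%, 89.6% and 98.5%, with 8 false of 186.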

Results

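RNA of mouse lung was measured on 29 single-colour microarrays. The mice were C57BL/6, wild type or without Klf15, and received dexamethasone, a synthetic glucocorticoid, at 2.5 mg/kg, or saline, for 4 or 8 h. Klf15 is a Krüppel-like transcription factor, and its gene is a known target of the glucocorticoid receptor. The wild-type groups held 4 arrays (saline, 4 h), 3 (saline, 8 h), 4 (dexamethasone, 4 h) and 3 (dexamethasone, 8 h), and the knockout groups 3, 4, 4 and 4 in the same order. By the series title, the design asks how the receptor and Klf15 together shape the course of gene expression through a feed-forward circuit. Each array held 43379 spots other than controls, of which 75.5 to 88.5% were well above background, and the number of arrays limits the precision of every value. The 75th percentile of the processed signal was 2719 ± 381 (SD, n = 14) on saline arrays and 2072 ± 238 (SD, n = 15) on dexamethasone arrays, and each array was scaled to its own. After the filter on dim probes, 15350 genes were tested. The labels call the samples biologic quadruplicates, so p-values measure the spread between such samples, of which 3 or 4 per group were analysed here. Changes are log2 differences with the adjusted p of limma, and genotype differences are knockout minus wild type. A bound written as "at least" is given where a gene was not well above background on any array of the lower group.

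Klf15 was lower on every knockout array than on any wild-type array. Its log2 signal relative to the array's 75th percentile was 2.34 ± 0.30 (SD, n = 4) and 2.98 ± 0.19 (SD, n = 3) in wild type under saline at 4 and 8 h. In the knockout it was -0.60 ± 0.35 (SD, n = 3) and -0.07 ± 0.52 (SD, n = 4). Under dexamethasone it was 4.27 ± 0.08 (SD, n = 4) and 3.77 ± 0.25 (SD, n = 3) in wild type, against 1.32 ± 0.12 (SD, n = 4) and 0.87 ± 0.32 (SD, n = 4) in the knockout. Single wild-type arrays lay between 2.05 and 4.37 and single knockout arrays between -0.82 and 1.45. The mean genotype difference for Klf15 was -2.96 (SE 0.11, adjusted p = 2.45e-15), and it was -2.94, -3.05, -2.95 and -2.91 in the saline 4 h, saline 8 h, dexamethasone 4 h and dexamethasone 8 h groups. The signal in the knockout was well above background on all arrays. A second Klf15 probe gave -2.64 for the mean genotype difference. Whether either probe lies in the deleted part of the gene is not given in the sources used here, and a probe outside it checks nothing. Dexamethasone raised the Klf15 signal by 1.93 (SE 0.206) in wild type and by 1.93 (SE 0.223) in the knockout at 4 h, and the difference between these effects was -0.01 (adjusted p = 0.991). By the second probe the rises were 1.93 and 1.26, with a difference of -0.67 (adjusted p = 0.0579). At 8 h the rises were 0.79 (adjusted p = 0.0178) and 0.93 (adjusted p = 0.000847). The wild-type rise at 8 h was 0.56 with slide as a block (adjusted p = 0.0715), and its call also ended without wild-type saline 8 h replicate 38 or without wild-type dexamethasone 8 h replicate 54 or 56.

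**Figure D1:**
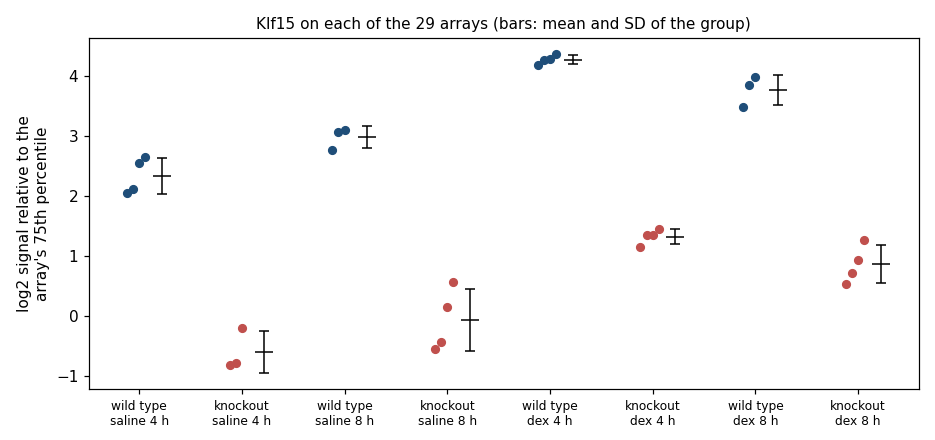
Klf15 log2 signal relative to each array's 75th percentile (vertical axis) for each of the 29 arrays (points), by group, with group means and SD. All wild-type arrays lie between 2.05 and 4.37 and all knockout arrays between -0.82 and 1.45.

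In wild-type lung at 4 h, dexamethasone raised glucocorticoid-induced genes. Fkbp5, a cochaperone that restrains the glucocorticoid receptor, rose by 3.07 (SE 0.44, adjusted p = 6.14e-06), and by 4.95 and 4.49 by its 2 other probes. Tsc22d3, the leucine zipper protein GILZ, rose by 1.54 (SE 0.14, adjusted p = 1.12e-08), the metallothionein Mt2 by 2.69 (adjusted p = 1.81e-10) and the clock repressor Per1 by 0.83 (adjusted p = 0.000508). Nr3c1, which encodes the receptor itself, fell by 0.81 (SE 0.0875, adjusted p = 1.03e-07). Among the largest rises, Doc2b, a calcium sensor of vesicle release, was at least 23-fold higher (adjusted p = 3.98e-11), the protease inhibitor Serpina3k at least 16.6-fold (adjusted p = 3.84e-06), and Fam107a, a stress-induced actin-binding protein, rose by 4.15 (SE 0.14). The potassium channel genes Kcnt1 and Kcnab1 rose by 4.74 and 3.84, while their dimmest probes gave -0.53 and -0.36 without a call. Greb1 rose by 3.83 (adjusted p = 0.000125). The largest falls were those of the lymphocyte chemokine Xcl1 (-3.70), the B cell antigen CD20 gene Ms4a1 (-3.47), the F4/80-related receptor Adgre4 (-3.46), the ligand gene Wnt7a (-3.45) and the B cell scaffold Bank1 (-3.38), and the interleukin 5 receptor chain Il5ra was at least 3.88-fold lower. In all, 5629 genes passed the test, 2197 higher and 3432 lower, of which 449 and 632 changed at least 2-fold.

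Of the glucocorticoid-induced genes at 4 h in wild type, 28 of 33 rose and 1 fell (28 and 1 adjusted over the list alone), adjusted p = 5.61e-21, adjusted p = 0.00145 with an estimated correlation. The cell-cycle inhibitor Cdkn1a rose by 3.04, the kinase Pdk4, which restrains pyruvate use, by 3.34, the kinase Map3k6 by 2.16 and glutamine synthetase Glul by 1.92. Of the lipid and glucose metabolism genes, 15 of 31 rose and 5 fell (15 and 5 adjusted over the list alone), adjusted p = 3.07e-05, adjusted p = 0.0975 with an estimated correlation; the lipase inhibitor Angptl4 rose by 1.80 and lipoprotein lipase Lpl by 1.68. Of the branched-chain amino acid catabolism genes, 7 of 21 rose and 1 fell (7 and 1 adjusted over the list alone), adjusted p = 0.0115, adjusted p = 0.0975 with an estimated correlation. The acyl-CoA dehydrogenases Acadsb and Ivd were at 0.80 and 0.55. Of the other amino acid catabolism genes, 13 of 34 rose and 8 fell (13 and 9 adjusted over the list alone), adjusted p = 0.038, adjusted p = 0.342 with an estimated correlation. In that list the glycine decarboxylase Gldc rose by 3.83, tyrosine aminotransferase Tat by 3.47, the lysine-degrading enzyme Aass by 0.96 (SE 0.0944, adjusted p = 2.46e-08) and proline dehydrogenase Prodh by 0.61 (SE 0.13, adjusted p = 0.000659). Aass, Prodh and Mt2 were named because the study is recalled to have discussed them, so they are not independent evidence. Of the circadian clock genes, 10 of 17 rose and 3 fell (11 and 5 adjusted over the list alone), adjusted p = 0.0148, adjusted p = 0.0975 with an estimated correlation; Tef rose by 1.11 and Per2 by 0.95, the latter without a call from its dimmest probe.

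Further lists passed as lower in this comparison with the preset correlation, and not with an estimated one. For T, B and NK cells, 0, 1 and 0 rose and 17, 12 and 13 fell of 22, 15 and 13 members (as many adjusted over the list alone). Their tests gave adjusted p = 1.25e-07, 5.16e-06 and 1.36e-05, and adjusted p = 0.19, 0.264 and 0.325 with an estimated correlation. Cd8a was at -2.01 and the T cell receptor chain Cd247 at -1.72, the B cell genes Cd79b and Cd22 at -2.15 and -1.77, and the NK cell receptors Ncr1 and Klrk1 at -3.26 and -1.75. Of the cytokine, chemokine and adhesion genes, 1 of 38 rose and 24 fell (1 and 25 adjusted over the list alone), adjusted p = 5.16e-06, adjusted p = 0.19 with an estimated correlation; the chemokine Ccl4 fell by 2.59, the growth factor Csf1 by 1.04 and the adhesion molecule Icam1 by 0.90. Of the interferon-stimulated genes, 0 of 25 rose and 19 fell (0 and 20 adjusted over the list alone), adjusted p = 3.9e-06, adjusted p = 0.268 with an estimated correlation. Ifit3 was at -1.59 and Irf7 at -0.97. Among genes of MHC class II presentation, 0 of 10 rose and 8 fell (0 and 8 adjusted over the list alone), adjusted p = 0.00136, adjusted p = 0.344 with an estimated correlation. H2-Ob was at -2.11 and the transactivator Ciita at -1.97. Of the endothelial markers, 2 of 15 rose and 11 fell (2 and 11 adjusted over the list alone), adjusted p = 0.00357, adjusted p = 0.239 with an estimated correlation. The growth factor receptors Kdr and Tek were at -1.36 and -0.92 and the junction gene Cldn5 at -0.93.

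The remaining lists did not pass in wild type at 4 h. Members higher and lower over all genes tested were 6 and 2 of 16 for epithelial ion and water transport (6 and 2 adjusted over the list alone, adjusted p = 0.0549), with the sodium pump subunit Atp1b1 at 1.25 and the kinase Sgk1 at 1.14. They were 3 and 8 of 19 for monocytes, interstitial macrophages and dendritic cells (3 and 9 adjusted over the list alone, adjusted p = 0.0956), 3 and 4 of 13 for alveolar macrophages (3 and 5, adjusted p = 0.814) and 3 and 3 of 17 for neutrophils (3 and 3, adjusted p = 0.961). The neutrophil list had a median of -0.21 and a mean of 0.05, which differ in sign. The counts were 0 and 5 of 12 for alveolar type 2 cells (0 and 5 adjusted over the list alone, adjusted p = 0.295), 3 and 3 of 10 for type 1 cells (4 and 3, adjusted p = 0.808), 3 and 1 of 14 for club and ciliated cells (2 and 1, adjusted p = 0.259) and 2 and 0 of 9 for smooth muscle (2 and 0, adjusted p = 0.503). For collagens and matrix they were 7 and 4 of 27 (7 and 4 adjusted over the list alone, adjusted p = 0.111), for the KLF family 3 and 2 of 15 (3 and 2, adjusted p = 0.503), for immediate-early genes 3 and 3 of 17 (3 and 3, adjusted p = 0.295), for heat shock genes 1 and 2 of 14 (1 and 1, adjusted p = 0.503) and for proliferation genes 3 and 6 of 28 (3 and 6, adjusted p = 0.859). Markers of tissues that could have come along with lung gave 0 and 1 of 10 for erythroid cells (0 and 1 adjusted over the list alone, adjusted p = 0.452), 2 and 1 of 13 for adipocytes (2 and 1, adjusted p = 0.452), 0 and 1 of 15 for heart (0 and 1, adjusted p = 0.503), 1 and 0 of 14 for skeletal muscle (0 and 0, adjusted p = 0.834) and 1 and 0 of 11 for thymus, thyroid, esophagus and liver (1 and 0, adjusted p = 0.589).

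In the fit with slide as a block, 6539 genes passed in wild type at 4 h, 5104 of them shared with the unblocked fit, and the median change was 1.27 for the glucocorticoid-induced genes and -2.26 for B cell markers, against 1.31 and -2.35 without the block. Within slides 3 and 7, which held 1 array of each group, those medians were 1.34 and -1.91, and 1.37 and -2.08, and 96.6% and 97.6% of the genes called without that slide had the same sign on it.

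At 8 h in wild-type lung, fewer of the glucocorticoid-induced genes passed than at 4 h. Mt2 rose by 1.60 (adjusted p = 1.51e-05), Tsc22d3 by 0.47 (adjusted p = 0.0393; 0.171 with slide as a block) and Prodh by 0.72 (adjusted p = 0.00103). Aass rose by 0.32 (adjusted p = 0.0356), a call that ended in 11 of the alternatives, among them leaving out any 1 of the 6 arrays compared. Per1 was at -0.08 (adjusted p = 0.823) and Nr3c1 at -0.26 (adjusted p = 0.0692). Fkbp5 was at -0.02 (adjusted p = 0.982) by its brightest probe, but at 1.21 (adjusted p = 0.000481) by the mean of its probes. The largest rises were those of Kcnt1 (4.28, with its dimmest probe at -0.07), Serpina3k (3.76, adjusted p = 0.000271), Doc2b (2.90, adjusted p = 1.72e-05), the chloride channel accessory genes Clca3a1 (2.81) and Clca3a2 (2.57) and Lrrc4 (2.44). The largest falls were those of Adgre4 (-4.21), the NK cell receptors Klra8 (-3.32) and Klra9 (-3.15), the serpin Serpinb10 (-3.24), the sphingosine phosphate receptor S1pr5 (-3.22) and the IgM receptor Fcmr (-3.19). In all, 3625 genes passed, 1430 higher and 2195 lower, of which 131 and 514 changed at least 2-fold.

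For the glucocorticoid-induced genes at 8 h in wild type, 14 of 33 rose and 0 fell (17 and 0 adjusted over the list alone), adjusted p = 3.58e-10, adjusted p = 0.0375 with an estimated correlation. For branched-chain amino acid catabolism, 6 of 21 rose and 0 fell (6 and 0 adjusted over the list alone), adjusted p = 0.000118, adjusted p = 0.0244 with an estimated correlation. The valine-degrading enzyme Aldh6a1 was at 0.96, Acadsb at 0.54 and the dehydrogenase subunit Bckdhb at 0.45, whose dimmest probe gave no call. With the preset correlation alone, other amino acid catabolism and lipid and glucose metabolism passed as higher, and the lists of T, B and NK cell markers, interferon-stimulated genes, MHC class II presentation and cytokines, chemokines and adhesion molecules passed as lower. Ifit3 was at -1.10, Irf7 at -1.09 and H2-Ab1 at -1.46. In the same way, immediate-early genes and club and ciliated cell markers passed as higher, and proliferation genes and markers of skeletal muscle, endothelium and monocytes as lower. Maff was at 1.07, Ier3 at 0.90, the troponin Tnni2 at -1.52 and the calcium channel Ryr1 at -1.12.

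In the fit with slide as a block, 3906 genes passed in wild type at 8 h, 3005 of them shared, and the median change was 0.43 for glucocorticoid-induced genes and -2.04 for B cell markers, against 0.40 and -2.35 without the block. Slide 1 alone held both groups, and on it those medians were 0.408 and -1.3, with the same sign in 93.3% of the 3121 genes called without it.

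The knockout saline arrays stood apart in the ratio between probes of the same gene. For 2546 genes with a bright and a dim probe more than 2 log2 units apart, both well above background on all arrays, the mean log2 ratio of bright to dim probe was lower on all 7 knockout saline arrays than on the 22 others. It ran from -0.368 to -0.116 on the former and from -0.0836 to 0.286 on the latter, a difference of -0.278 (two-sided exact permutation p = 6.41e-07, the smallest the design can give). After quantile normalization the difference was -0.191 (exact permutation p = 8.33e-06), and 3 other arrays lay below the highest knockout saline array. On each of the 6 slides with knockout saline arrays, these lay below the slide's other arrays. These 7 arrays enter every comparison between genotypes under saline and every dexamethasone effect in the knockout. Among genes called by the bright probe, the dim probe moved in the same direction in 83.2% in wild type under dexamethasone at 4 h and 84.7% at 8 h. The shares were 61.1% and 60.4% in the knockout, and 40.5% and 47% in the genotype comparisons under saline (71.2%, 70.4%, 56.3% and 56.3% after quantile normalization). Among knockout calls of at least 2-fold they were 99.1% and 96%.

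**Figure D2:**
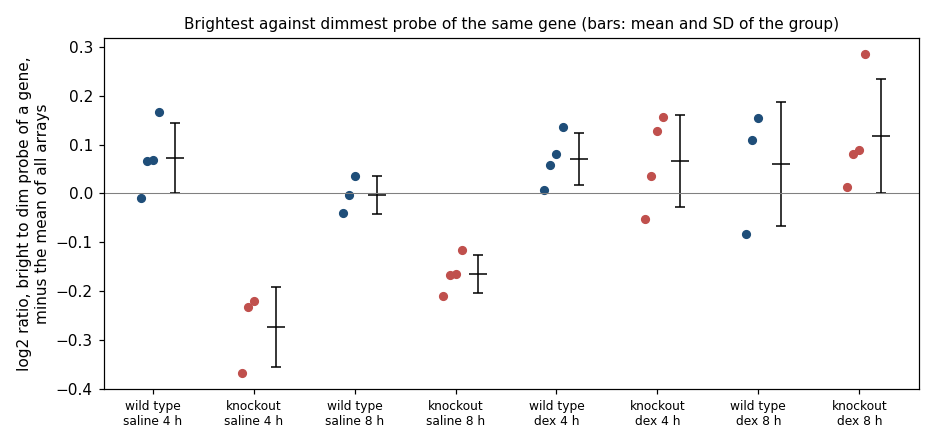
Mean log2 ratio of the brightest to the dimmest probe of a gene on each array (vertical axis, relative to the mean of all arrays), over 2546 genes, by group; points are the 29 arrays. The 7 knockout saline arrays lie between -0.368 and -0.116, below all 22 others.

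In knockout lung at 4 h, dexamethasone raised most of the glucocorticoid-induced genes. Fkbp5 rose by 4.23 (SE 0.475, adjusted p = 1.92e-07), Tsc22d3 by 1.71 (adjusted p = 2.17e-08), Mt2 by 2.22 (adjusted p = 1.39e-08), Aass by 0.88 (adjusted p = 3.05e-07) and Per1 by 0.99 (adjusted p = 0.000153). Prodh was at 0.15 (adjusted p = 0.442), and Nr3c1 fell by 0.33 (adjusted p = 0.00704) by its brightest probe, with its 3 other probes at -1.63, -1.06 and -0.85. The largest rises were Doc2b (at least 27.9-fold), Serpina3k (at least 13.9-fold), the potassium channel gene Kcnv2 (at least 5.85-fold), Fam107a (4.33) and Kcnt1 (4.23, with no call from its dimmest probe). The largest falls were Apol7c (-3.61), Syt15 (-3.60), the interferon-induced GTPase Gbp4 (-3.52), Xcl1 (-3.43), the laminin Lama1 (at least 6.32-fold) and the chemokine Ccl22 (-3.21, adjusted p = 0.00157). In all, 6550 genes passed, 3842 higher and 2708 lower, of which 487 and 575 changed at least 2-fold. The share of higher calls was 58.66%, and 47.99% in the deposited table.

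Of the glucocorticoid-induced genes at 4 h in the knockout, 27 of 33 rose and 1 fell (27 and 1 adjusted over the list alone), adjusted p = 2.84e-14, adjusted p = 0.0123 with an estimated correlation. For lipid and glucose metabolism, 16 of 31 rose and 2 fell (16 and 3 adjusted over the list alone), adjusted p = 0.00332, adjusted p = 0.317 with an estimated correlation. Branched-chain amino acid catabolism did not pass: 7 of 21 rose and 3 fell (7 and 3 adjusted over the list alone), adjusted p = 0.388. Nor did other amino acid catabolism: 10 of 34 rose and 11 fell (10 and 11 adjusted over the list alone), adjusted p = 0.989. For the cytokine, chemokine and adhesion genes, 0 of 38 rose and 22 fell (0 and 22 adjusted over the list alone), adjusted p = 7.62e-07, adjusted p = 0.275 with an estimated correlation. Ccl4 was at -2.74, Icam1 at -1.42 and Csf1 at -1.09. Interferon-stimulated genes, MHC class II presentation and endothelial markers passed as lower, and not with an estimated correlation. Markers of T, B and NK cells and the list of monocytes, interstitial macrophages and dendritic cells passed as lower with the preset correlation alone. Klf9, another receptor target of the KLF family, rose by 1.04 and Klf4 by 0.92, and the matrix genes Ccn2 and Timp3 rose by 1.42 and 1.10.

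With slide as a block, 7653 genes passed in the knockout at 4 h, 6014 of them shared, and the median change was 1.68 for glucocorticoid-induced genes and -1.78 for B cell markers, against 1.69 and -1.68; on slide 4, which held both groups, these medians were 1.45 and -1.13. The knockout saline arrays had the lowest ratio of bright to dim probe, and with that ratio as a covariate 4372 genes passed, 3290 of them shared, while Per1 (0.70 with it, adjusted p = 0.0662) and Ccl22 (-2.48, adjusted p = 0.12) lost their calls, with a median SE 1.5 times as large.

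At 8 h in knockout lung, Mt2 rose by 2.19 (adjusted p = 7.66e-09), Fkbp5 by 1.32 (adjusted p = 0.0185), Tsc22d3 by 0.58 (adjusted p = 0.00192) and Aass by 0.35 (adjusted p = 0.00457). Prodh was at 0.29 (adjusted p = 0.0787) and Per1 at -0.06 (adjusted p = 0.813), and Nr3c1 fell by 0.26 (adjusted p = 0.0179) by its brightest probe, with the 3 others at -1.36, -0.95 and -0.59. The calls of Nr3c1 and Fkbp5 ended without knockout saline 8 h replicate 45 (-0.22 and 1.18) or knockout dexamethasone 8 h replicate 61 (-0.21 and 1.18), while the 2 other Fkbp5 probes gave 2.34 and 2.13 (adjusted p = 2.91e-10 and 3.57e-08). The largest rises were those of Kcnt1 (4.68) and Kcnab1 (3.44), neither called by its dimmest probe, Doc2b (4.45), Serpina3k (3.94), the acute-phase protein Orm2 (3.46) and Clca3a1 (3.45). The largest falls were those of Adgre4 (-4.07), Gbp4 (-3.63), S1pr5 (-3.54) and the peptide ligand Apln (-3.47), and the macrophage elastase Mmp12 and the carbonic anhydrase Car12 were at least 9.98-fold and at least 4.87-fold lower. In all, 6608 genes passed, 3965 higher and 2643 lower, or 60% higher. The median of all genes was shifted by 0.110, and with quantile normalization 2807 were higher and 3040 lower, or 48.01% higher.

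For the glucocorticoid-induced genes at 8 h in the knockout, 26 of 33 rose and 1 fell (28 and 1 adjusted over the list alone), adjusted p = 8.04e-10, adjusted p = 0.0765 with an estimated correlation, and their median relative to that of all genes was 0.94. For lipid and glucose metabolism, 18 of 31 rose and 0 fell (21 and 2 adjusted over the list alone), adjusted p = 4.71e-05, adjusted p = 0.13 with an estimated correlation. Pdk4 was at 2.47, Lpl at 1.93, the phosphatidate phosphatase Lpin1 at 1.87 and Angptl4 at 1.68. For epithelial ion and water transport, 10 of 16 rose and 1 fell (10 and 2 adjusted over the list alone), adjusted p = 0.0463, adjusted p = 0.159 with an estimated correlation. Sgk1 was at 1.27 and Atp1b1 at 1.17. For adipocyte markers, 8 of 13 rose and 0 fell (9 and 0 adjusted over the list alone), adjusted p = 0.0118, adjusted p = 0.41 with an estimated correlation. Adipsin Cfd was at 2.59, the fatty acid binding protein Fabp4 at 2.24 and the lipid droplet protein Cidec at 1.10. Club and ciliated cell markers and immediate-early genes passed as higher with the preset correlation alone. Markers of T, B and NK cells and monocytes, interferon-stimulated genes, MHC class II presentation, cytokines and endothelial markers passed as lower with it alone, too. Relative to the median of all genes, the lists' medians were 0.44 for lipid and glucose metabolism, 0.44 for club and ciliated cells, -1.36 for T cells and -2.16 for B cells.

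With slide as a block, 8344 genes passed in the knockout at 8 h, 6313 of them shared, and on slides 3 and 7, which held both groups, the glucocorticoid-induced genes had medians of 1.11 and 0.782 and the B cell markers of -1.36 and -2.44, against 1.04 and -1.99 with the block. The knockout saline arrays had the lowest ratio of bright to dim probe, and with that ratio as a covariate 5349 genes passed, 3662 of them shared, while Fkbp5 (1.21 with it, adjusted p = 0.153) and Aass (0.15, adjusted p = 0.385) lost their calls, with a median SE 1.41 times as large.

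The dexamethasone effects in both genotypes use different arrays. Across all 15350 genes, which are not independent replicates, they correlated with Pearson's r = 0.652 at 4 h and 0.564 at 8 h. At 4 h, 1590 genes rose in both genotypes, against 549.9 from independent lists, 1813 fell in both, against 605.5, and 143 were called in opposite directions. At 8 h, 1114 rose in both, against 369.4, 1447 fell in both, against 377.9, and 37 went in opposite directions. Over both genotypes and times, 786 genes rose and 951 fell in all 4 comparisons.

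**Figure D3:**
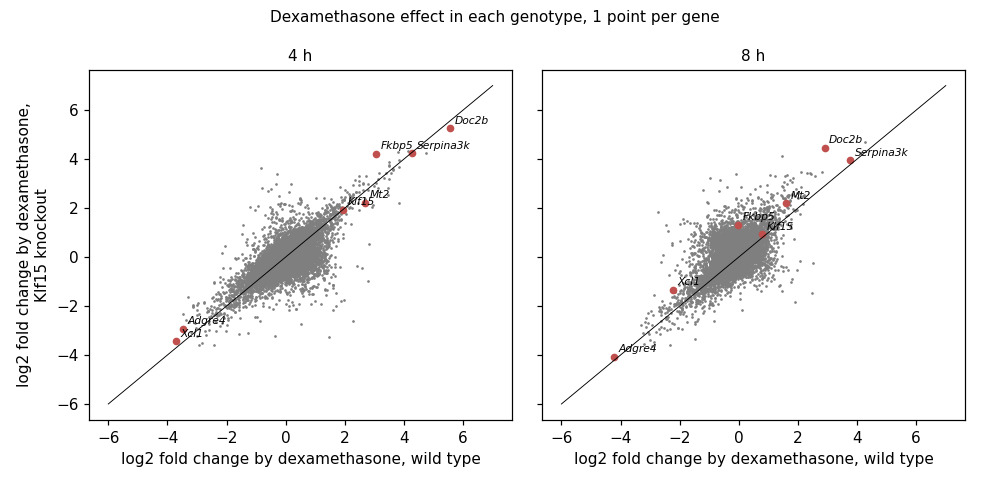
Log2 change under dexamethasone in wild type (horizontal axis) against the knockout (vertical axis) at 4 h and at 8 h; each point is 1 of the 15350 genes tested, named genes are red, and the line marks equal changes. Pearson's r across genes is 0.652 at 4 h and 0.564 at 8 h.

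Under dexamethasone, where the knockout saline arrays enter only the shared estimate of the spread, lungs without Klf15 had lower levels of genes of amino acid breakdown. At 4 h Aass was lower, at -1.14 (SE 0.0944, adjusted p = 3.29e-08), with log2 levels of 1.33 ± 0.153 (SD, n = 4) in wild type and 0.19 ± 0.205 (SD, n = 4) in the knockout. Prodh was lower, at -1.45 (SE 0.13, adjusted p = 1.31e-07), at 3.05 ± 0.25 (SD, n = 4) against 1.60 ± 0.271 (SD, n = 4). The largest falls other than Klf15 were those of the oxoacid transhydrogenase Adhfe1 (at least 12.9-fold, with no call from its dimmest probe), the secreted zinc-binding glycoprotein Azgp1 (-4.30), the sulfate transporter Slc13a4 (-3.82), cystathionine beta-synthase Cbs (-3.12) and Lrtm2 (-2.88). The matrix gene fibulin 2, Fbln2, was higher by 2.24 (adjusted p = 1.59e-08) and the neuropeptide receptor Adcyap1r1 by 2.05 (adjusted p = 0.000136), the latter without a call from its dimmest probe. The neurotensin receptor Ntsr2 was higher by 1.65 (adjusted p = 0.011), and the olfactory receptor genes Olfr354 and Olfr1156 were at least 1.73-fold and 1.53-fold higher. Mt2 was at 0.20 (adjusted p = 0.798) and Nr3c1 at 0.05 (adjusted p = 0.918). In all, 149 genes passed, 53 higher and 96 lower (28 and 92 in the deposited table), and with only the groups compared 75 passed, without Ntsr2 and Ppm1k. The call of Olfr354 ended in 18 alternatives, among them leaving out any of the 8 arrays compared, and that of Olfr1156 in 9, 4 of them leaving out a single array.

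For branched-chain amino acid catabolism under dexamethasone at 4 h, 0 of 21 were higher and 5 were lower (0 and 10 adjusted over the list alone), adjusted p = 7.18e-13, adjusted p = 1.67e-05 with an estimated correlation. Aldh6a1 was at -1.11, the phosphatase Ppm1k at -0.80, Bckdhb at -0.66 and Ivd at -0.57. For other amino acid catabolism, 0 of 34 were higher and 10 were lower (1 and 13 adjusted over the list alone), adjusted p = 1.98e-15, adjusted p = 0.000414 with an estimated correlation. The last enzymes of tyrosine breakdown, Fah and Gstz1, were at -0.93 and -0.85. For circadian clock genes, 0 of 17 were higher and 1 was lower (0 and 2 adjusted over the list alone), adjusted p = 8.25e-05, adjusted p = 0.00241 with an estimated correlation. For the KLF family, from which Klf15 was left out, 0 of 15 were higher and 1 was lower (0 and 1 adjusted over the list alone), adjusted p = 0.00802, adjusted p = 0.411 with an estimated correlation. Immediate-early genes passed as a list with 0 called members (adjusted p = 0.0415, and adjusted p = 0.89 with an estimated correlation). No slide held both groups at 4 h. In the fit blocked by slide, 170 genes passed, 103 of them shared, and Ntsr2, Olfr354 and Olfr1156 lost their calls (adjusted p = 0.0785, 0.208 and 0.121). The medians with the block were -0.20 for branched-chain and -0.09 for other amino acid catabolism, against -0.15 and -0.11 without it, and without wild-type dexamethasone 4 h replicate 51 the count was 92.

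At 8 h under dexamethasone the same enzymes were lower without Klf15. Aass was lower, at -1.11 (SE 0.102) and Prodh at -1.46 (SE 0.14, adjusted p = 3.69e-07). Adhfe1 and the acetyltransferase family gene Nat8f5 were at least 21.1-fold and at least 7.07-fold lower, the former with no call from its dimmest probe, and Azgp1 (-4.80), Slc13a4 (-4.63), Lrtm2 (-3.75) and Cbs (-3.55) fell. Fbln2 was higher by 2.60 (adjusted p = 3.56e-09), Lrrc10 by 2.49 (adjusted p = 0.0097), Adcyap1r1 by 2.16, Ntsr2 by 1.94, the chemokine Ccl8 by 1.63 and cholecystokinin Cck by 1.59 (adjusted p = 0.0271). Mt2 was higher by 1.13 (adjusted p = 0.00255) and Nr3c1 was at -0.20 (adjusted p = 0.201). In all, 760 genes passed, 464 higher and 296 lower. With only the groups compared 50 passed, and Cdkn1a, Mt1, Mt2, Tgm2, Mmp2, Col6a2, Ccl8, Ntsr2, Lrrc10, Cck and Ivd lost their calls. Of those called under dexamethasone at 4 h, on other arrays, 20 were also higher at 8 h, against 1.602 from independent lists, and 76 also lower, against 1.851, while over all 15350 genes Pearson's r between the 2 times was 0.0771. Without wild-type dexamethasone 8 h replicate 55 Lrrc10 and Cck were at 1.61 and 1.37 and lost their calls, as did Cck without replicate 54 (1.62) or knockout replicate 61 or 64 (1.60 and 1.56).

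For branched-chain amino acid catabolism at 8 h under dexamethasone, 0 of 21 were higher and 7 were lower (0 and 10 adjusted over the list alone), adjusted p = 1.14e-09, adjusted p = 0.000112 with an estimated correlation. The dehydrogenase subunits Dbt and Bckdhb were at -1.64 and -1.23, Aldh6a1 at -1.54 and Ivd at -0.74. For other amino acid catabolism, 2 of 34 were higher and 13 were lower (2 and 14 adjusted over the list alone), adjusted p = 5.64e-07, adjusted p = 0.0313 with an estimated correlation. Fah was at -1.15 and Gstz1 at -0.97. For glucocorticoid-induced genes, 9 of 33 were higher and 0 were lower (11 and 2 adjusted over the list alone), adjusted p = 0.000158, adjusted p = 0.289 with an estimated correlation. Cdkn1a was at 1.18, Mt1 at 0.87 and the transglutaminase Tgm2 at 0.43. For smooth muscle, 3 of 9 were higher and 0 were lower (7 and 0 adjusted over the list alone), adjusted p = 0.000467, adjusted p = 0.289 with an estimated correlation. The myosin Myh11 was at 0.69. For collagens and matrix, 5 of 27 were higher and 0 were lower (7 and 0 adjusted over the list alone), adjusted p = 0.00215, adjusted p = 0.72 with an estimated correlation. Mmp2 was at 1.18 and Col6a2 at 0.79. Interferon-stimulated genes, MHC class II presentation, the KLF family, immediate-early genes, heart and adipocyte markers passed with the preset correlation and not with an estimated one. No slide held both groups. In the fit blocked by slide, 414 genes passed, 275 of them shared, 2 glucocorticoid-induced and 0 smooth muscle genes were called higher, and Mt2, Mt1, Ccl8 and Myh11 lost their calls (adjusted p = 0.0562, 0.0802, 0.0653 and 0.0664). The medians with the block were -0.22 for branched-chain and -0.12 for other amino acid catabolism, against -0.27 and -0.16, and the count was 303 without wild-type dexamethasone 8 h replicate 55 and 1160 without knockout dexamethasone 8 h replicate 62.

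The genotype comparison under saline at 4 h rests on the arrays with the lowest ratio of bright to dim probe, and no list passed in it. Aass was lower, at -1.05 (SE 0.102, adjusted p = 8.31e-07) and Prodh at -0.99 (SE 0.14, adjusted p = 0.00014). The largest falls other than Klf15 were those of Azgp1 (-4.20), Slc13a4 (-4.04), Adhfe1 (-3.98), Lrtm2 (-2.77) and the glycine methyltransferase Gnmt (-2.10). Of the rises, Fbln2 was at 2.2, and genes not well above background in wild type have bounds only. These are at least 4.06-fold (the 2-hydroxyacyl-CoA lyase Hacl1), 4.41-fold (Ccl22), 3.56-fold (Nr2f1), 3.52-fold (Gfod1), 3.27-fold (Acsbg2) and 2.3-fold (Rgmb). The 2073 genes not well above background on all arrays shifted as a class, with a median of 0.489, against -0.0712 for the others, and 58 of them were called at least 2-fold higher and 3 lower. Of the spots, 84.1% were well above background on these knockout arrays and 78.5% on the wild-type ones. Mt2 was higher by 0.66 (adjusted p = 0.0239; 0.0634 with slide as a block), but by 0.34 without knockout saline 4 h replicate 41, where its call ended. Nr3c1 was lower, at -0.43 (adjusted p = 0.00281) by its brightest probe, but higher by the 3 others (0.82, 0.37 and 0.31, adjusted p = 0.0019, 0.0108 and 0.0298). For branched-chain amino acid catabolism, 1 of 21 was higher and 10 were lower (1 and 10 adjusted over the list alone), adjusted p = 0.096. Aldh6a1 was at -1.33, Ivd at -0.79, Mccc1 at -0.62 and Bckdhb at -0.54. For other amino acid catabolism, 0 of 34 were higher and 8 were lower (0 and 10 adjusted over the list alone), adjusted p = 0.096. Cbs was at -1.65, the cystathionine lyase Cth at -1.16 and Gstz1 at -0.50. T cell markers had the lowest adjusted p: 0 of 22 were higher and 9 were lower (0 and 10 adjusted over the list alone), adjusted p = 0.0678. Cd6 was at -1.10 and Cd5 at -1.04. For the KLF family, 0 of 15 were higher and 6 were lower (0 and 7 adjusted over the list alone), adjusted p = 0.096. Klf6 was at -0.62. In all, 3842 genes passed, 931 higher and 2911 lower, or 24.23% higher, against 29.49% with quantile normalization and 38.52% in the deposited table.

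No slide held both saline groups at 4 h. In the fit blocked by slide, 3408 genes passed, 2027 of them shared, Hacl1, Ccl22, Nr2f1, Gfod1 and Rgmb lost their calls (adjusted p = 0.564, 0.0802, 0.628, 0.287 and 0.762, with Rgmb at -0.13), and the median of branched-chain amino acid catabolism was -0.19, against -0.20. With the ratio of bright to dim probe as a covariate 21 genes passed, all among the 3842, including Klf15, Gnmt, Cbs, Lrtm2, Fbln2, Azgp1, Slc13a4, Adhfe1, Aldh6a1, Cth, Bckdhb, Ivd and Aass, while Prodh (-0.56 with it, adjusted p = 0.286), Gstz1 (-0.44), Mccc1 (-0.23), Cd5 (-0.88), Cd6 (-0.82), Klf6 (-0.48), Mt2 (0.96) and Nr3c1 (-0.19) did not. The median SE was 1.52 times as large. The calls of Rgmb, Nr2f1, Acsbg2, Gfod1 and Hacl1 ended in 17, 12, 12, 10 and 9 alternatives, of which 7, 4, 6, 4 and 3 left out a single array.

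At 8 h under saline, Aass was lower in the knockout, at -1.14 (SE 0.102, adjusted p = 1.8e-07) and Prodh at -1.02 (SE 0.14, adjusted p = 0.000117). Azgp1 (-4.27), Adhfe1 (-3.96) and Slc13a4 (-3.56) had large falls, and the keratin Krt27, Zfp36l3 and the Kupffer cell lectin Clec4f were at least 6.78-fold, 4.44-fold and 4.93-fold lower. Fbln2 (2.06), Ptov1 (1.54), the farnesyltransferase subunit Fntb (1.35), Adcyap1r1 (1.17), Trappc10 (1.14) and Mxra7 (1.09) had the largest rises, of which Fntb and Adcyap1r1 were at -0.026 and -0.81 by their dimmest probes. Mt2 was at 0.54 (adjusted p = 0.0848; 0.73 and 0.0404 with slide as a block) and Nr3c1 at -0.19 (adjusted p = 0.173), but at 0.98, 0.32 and 0.23 by its 3 other probes, the first 2 called. In other amino acid catabolism, 0 of 34 were higher and 8 were lower (0 and 8 adjusted over the list alone), adjusted p = 0.00938, adjusted p = 0.461 with an estimated correlation. Cbs was at -2.63, Cth at -0.93 and Gstz1 at -0.53. In branched-chain amino acid catabolism, 0 of 21 were higher and 6 were lower (1 and 7 adjusted over the list alone), adjusted p = 0.0726. For endothelial markers, 4 of 15 were higher and 0 were lower (6 and 0 adjusted over the list alone), adjusted p = 0.00938, adjusted p = 0.461 with an estimated correlation. The adhesion molecule Pecam1 was at 0.50 and the receptor Tie1 at 0.46. For interferon-stimulated genes, 1 of 25 was higher and 0 were lower (1 and 0 adjusted over the list alone), adjusted p = 0.0178, adjusted p = 0.952 with an estimated correlation. The median of all genes was shifted by -0.126, and relative to it the lists' medians were -0.12 for other amino acid catabolism, -0.12 for branched-chain amino acid catabolism, 0.21 for endothelial markers and 0.22 for interferon-stimulated genes. In all, 2117 genes passed, 772 higher and 1345 lower, or 36.47% higher, against 61.82% with quantile normalization.

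With slide as a block, 4073 genes passed under saline at 8 h, 1974 of them shared, Zfp36l3 lost its call (adjusted p = 0.094), and on slide 1, the single one with both groups, the medians of branched-chain and other amino acid catabolism were -0.212 and -0.159, against -0.21 and -0.20 with the block. With the bright-to-dim ratio as a covariate 2326 passed, 1096 of them shared. Without wild-type saline 8 h replicate 39 the count was 919 and Ptov1, Adcyap1r1, Clec4f and Zfp36l3 lost their calls. Those of Clec4f and Zfp36l3 ended in 12 and 11 alternatives, 6 of them each time leaving out a single array, and the dim class of genes had a median of -0.616 in this comparison.

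Averaged over the 4 groups, genes of amino acid breakdown and a few secreted and transport proteins were among those lower without Klf15. Aass was at -1.11 (SE 0.05, adjusted p = 9.83e-14) and Prodh at -1.23 (SE 0.0689, adjusted p = 5.48e-12). Adhfe1 (-4.59), Azgp1 (-4.39), Slc13a4 (-4.01), Lrtm2 (-3.03) and Cbs (-2.74) fell most beside Klf15. Of genes without array overlap, Fbln2 (2.28, adjusted p = 2.08e-14) and Adcyap1r1 (1.84, no call by its dimmest probe) rose most. Mindy4 (0.78), Gdpd2 (0.62), Prmt8 (0.56) and Exoc4 (0.45) came next. Mt2 was at 0.64 (adjusted p = 0.000205). Nr3c1 was at -0.19 (adjusted p = 0.00595), but 0.35, 0.13 and 0.076 by its 3 other probes. In branched-chain amino acid catabolism, 0 of 21 were higher and 9 were lower (1 and 11 adjusted over the list alone), adjusted p = 4.92e-07, adjusted p = 0.000891 with an estimated correlation. Aldh6a1 was at -1.32, Bckdhb at -0.77 and Ivd at -0.73. In other amino acid catabolism, 0 of 34 were higher and 13 were lower (0 and 13 adjusted over the list alone), adjusted p = 1.86e-06, adjusted p = 0.0434 with an estimated correlation. Cth was at -1.03 and Gstz1 at -0.71. For immediate-early genes, 0 of 17 were higher and 8 were lower (0 and 10 adjusted over the list alone), adjusted p = 0.00133, adjusted p = 0.6 with an estimated correlation. The nuclear receptor Nr4a1 was at -0.63. For T cells, 0 of 22 were higher and 10 were lower (0 and 10 adjusted over the list alone), adjusted p = 0.0098, adjusted p = 0.808 with an estimated correlation. Cd5 was at -0.49 and Cd3g at -0.43. For interferon-stimulated genes, 6 of 25 were higher and 0 were lower (6 and 0 adjusted over the list alone), adjusted p = 0.0037, adjusted p = 0.808 with an estimated correlation. Irf7 was at 0.58. The KLF family, collagens and matrix, and heart markers passed with the preset correlation alone.

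In the mean genotype difference 2982 genes passed, 1270 higher and 1712 lower, or 42.59% higher, against 54.57% in the deposited table. In the fit blocked by slide, 5232 passed, 2974 of them shared, with medians of -0.14 for branched-chain and -0.07 for other amino acid catabolism, against -0.15 and -0.07; with the ratio of bright to dim probe, lowest on the knockout saline arrays, as a covariate 1180 passed, 965 of them shared, and Nr4a1 (-0.46), Cd3g (-0.41), Nr3c1 (-0.11) and Vmn1r53 lost their calls, with a median SE 1.25 times as large. Called as lower in each of the 4 genotype comparisons were 46 genes, among them Aass, Prodh, Cbs, Cth, Gnmt, Fah, Gstz1, Ivd, Bckdhb, Aldh6a1, Adhfe1, Azgp1 and Slc13a4, and called as higher in each were 3, Fbln2, Adcyap1r1 and Mindy4. Klf15 lies on chromosome 6, and 146 of its neighbours within 10 Mb were tested. Of these 33 passed, or 22.6%, against 19.4% of 15203 other genes (two-sided Fisher's exact p = 0.344). At least 2-fold different were 4 of the neighbours, against 26 genes elsewhere (two-sided Fisher's exact p = 0.000178): Fbln2 (2.28), the folate enzyme Aldh1l1 (-1.44), Nat8f5 (-2.59) and the vomeronasal receptor Vmn1r53 (1.34, and 0.65 with the covariate, adjusted p = 0.216).

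**Figure D4:**
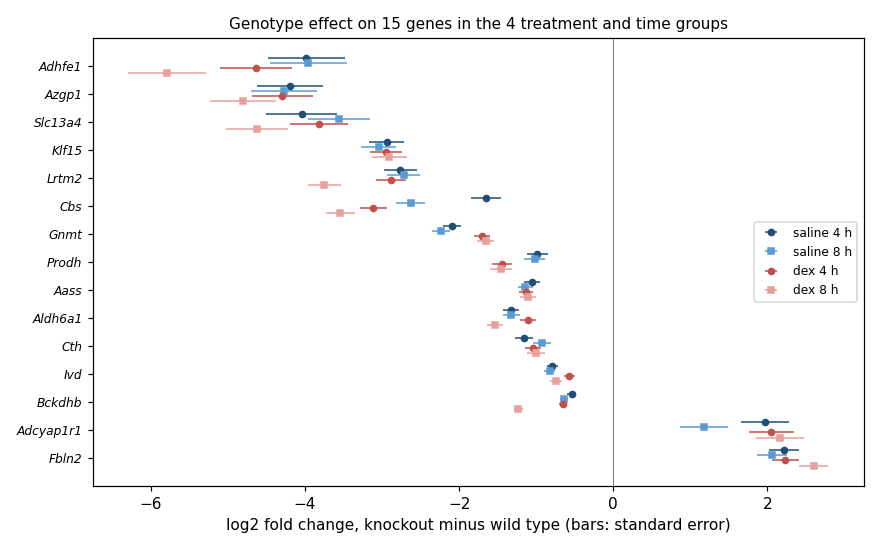
Log2 difference, knockout minus wild type (horizontal axis), of genes named for the genotype comparisons, a point per treatment and time with SE bars. Aass and Prodh were lower in each, with mean differences of -1.11 and -1.23.

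Whether the response to dexamethasone differed between genotypes was tested directly. At 4 h the effects on Aass and Prodh differed by -0.08 (adjusted p = 0.734) and -0.46 (adjusted p = 0.0998), and at 8 h by 0.03 (adjusted p = 0.915) and -0.43 (adjusted p = 0.177). Averaged over both times, the Prodh response was smaller in the knockout by -0.45 (SE 0.138, adjusted p = 0.0174), and that of Aass differed by -0.03 (adjusted p = 0.886). Fah was at 0.27 and 0.42 in wild type (4 and 8 h), -0.44 and -0.37 in the knockout. These differed by -0.72, -0.79 and -0.75 in the mean (adjusted p = 9.9e-06). Bckdhb differed by -0.59 at 8 h and -0.35 in the mean, neither called by its dimmest probe. Among the genes with the lowest adjusted p, the ubiquitin ligase Peli1 (0.71), the demethylase Kdm1a (0.74) and Klf6 (0.67) had a higher response in the knockout at 4 h, and the transcription factor Nfe2l1 (0.59), malate dehydrogenase Mdh2 (0.66), the amino acid transporter Slc38a4 (1.34) and fatty acid synthase Fasn (0.87) at 8 h. Mdh2 and Fasn lost these calls with quantile normalization, and Mdh2 and Nfe2l1 in the deposited table. Nr3c1 was at 0.48 at 4 h by its brightest probe (adjusted p = 0.0153) and at -0.97, -0.40 and -0.36 by the 3 others. For branched-chain amino acid catabolism at 8 h, 0 of 21 were higher and 4 were lower (0 and 5 adjusted over the list alone), adjusted p = 0.0144, adjusted p = 0.108 with an estimated correlation. For glucocorticoid-induced genes at 8 h, 4 of 33 were higher and 1 was lower (10 and 1 adjusted over the list alone), adjusted p = 0.0167, adjusted p = 0.87 with an estimated correlation. For other amino acid catabolism at 4 h, 1 of 34 was higher and 3 were lower (1 and 3 adjusted over the list alone), adjusted p = 0.0424, adjusted p = 0.999 with an estimated correlation. In the mean, these lists gave 0.103, 0.444 and 0.0891 as adjusted p.

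At 4 h, 2605 genes passed the test of the difference in response, 2121 higher and 484 lower (81.42% higher, 52.26% in the deposited table). At 8 h 1002 passed, 755 higher and 247 lower (75.35%, 47.76% with quantile normalization). In the mean 4538 passed, 3502 higher and 1036 lower (77.17%, 57.62% in the deposited table). The median of all genes was shifted by 0.105, 0.155 and 0.135, and relative to these shifts the branched-chain amino acid list had medians of -0.05, -0.21 and -0.12 and the glucocorticoid-induced list of 0.07, 0.37 and 0.18. In the slide-blocked fits 2423, 445 and 3893 passed, and with the ratio of bright to dim probe, which was lowest on the knockout saline arrays, as a covariate 3, 293 and 480. In that covariate fit, Peli1 (0.55), Kdm1a (0.50), Klf6 (0.54) and Nr3c1 (0.24) lost their calls at 4 h (median SE 1.29 times as large). Cbs in the mean went from -1.19 to -0.73 (adjusted p = 0.068), and Fah and the other genes called above kept theirs. Without knockout saline 4 h replicate 43 the count at 4 h was 1310, and without wild-type dexamethasone 8 h replicate 55 that at 8 h was 356.

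In both genotypes many glucocorticoid-induced genes had a smaller dexamethasone effect at 8 h than at 4 h. Part of this lay in higher saline levels (knockout Tsc22d3, 3.475 to 4.537), part in lower levels under dexamethasone (knockout Aass, 0.19 to -0.35). In wild type the effect was lower at 8 h by -3.09 for Fkbp5 (adjusted p = 0.00561), -2.26 for Fam107a, -1.14 for Klf15 (adjusted p = 0.0305), -1.09 for Mt2, -1.08 for Tsc22d3, -0.91 for Per1 and -0.64 for Aass. The ubiquitin ligase gene Sh3rf2 (2.08) and Nr3c1 (0.56, without a call from its 3 other probes) moved the other way. In the knockout it was lower, at -2.91 for Fkbp5, -1.82 for Fam107a, -1.13 for Tsc22d3, -1.05 for Per1 and -0.53 for Aass, while Klf15 was at -0.99 (adjusted p = 0.0841) and Mt2 at -0.03 (adjusted p = 0.987). Of the glucocorticoid-induced genes, in wild type 1 of 33 was higher and 17 were lower (1 and 25 adjusted over the list alone), adjusted p = 8.07e-18, adjusted p = 0.00375 with an estimated correlation. In the knockout 1 of 33 was higher and 9 were lower (1 and 17 adjusted over the list alone), adjusted p = 3.69e-11, adjusted p = 0.0393 with an estimated correlation. Clock genes, cytokines, matrix and heat shock genes in wild type, and cytokines and markers of T cells, adipocytes and heart in the knockout, passed with the preset correlation alone. In all, 923 genes passed in wild type, 441 higher and 482 lower, and 463 in the knockout, 188 higher and 275 lower. Blocking by slide gave counts of 1504 and 680, with 863 and 400 shared; the medians of the glucocorticoid-induced genes were -0.81 and -0.48, against -0.79 and -0.56, and Mt2 lost its wild-type call (adjusted p = 0.0773). The counts were 605 without wild-type dexamethasone 8 h replicate 55 and 277 without knockout saline 4 h replicate 41, and the calls of Klf15, Per1 and Mt2 in wild type and of Aass in the knockout each ended when any of several single arrays was left out. In the knockout, without saline 4 h replicate 41 Fkbp5 (-2.45) and Per1 (-0.84) lost theirs, as did Per1 without dexamethasone 4 h replicate 58 (adjusted p = 0.0512).

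Under saline, clock genes and glucocorticoid-induced genes differed between 8 h and 4 h, over both genotypes. The clock repressors Per2, Cry1 and Per1 were higher at 8 h by 1.10, 0.996 and 0.68 and the deubiquitinase Usp2 by 0.97 (Per2 and Cry1 without a call from their dimmest probes, Per1 without one when only the groups compared were fitted), and the activator Arntl was lower, at -0.84. Fam107a was higher by 1.41, Gldc by 1.61, Tsc22d3 by 0.94 (adjusted p = 1.04e-05), Map3k6 by 0.91, Fkbp5 by 1.23 (adjusted p = 0.0456), Glul by 0.60 and Klf15 by 0.59 (adjusted p = 0.0402), and the matrix protein Spon2 was lower, at -1.96. For clock genes, 8 of 17 were higher and 3 were lower (8 and 4 adjusted over the list alone), adjusted p = 2.61e-06, adjusted p = 0.00119 with an estimated correlation. Among glucocorticoid-induced genes, 13 of 33 were higher and 0 were lower (15 and 0 adjusted over the list alone), adjusted p = 2.31e-17, adjusted p = 0.00217 with an estimated correlation. The KLF family, cytokines and heart markers, and further lists in the interaction and time comparisons, passed with the preset correlation and not with an estimated one. In all, 500 genes passed, 319 higher and 181 lower. Blocking by slide, 878 passed, 447 of them shared, the medians were 0.38 for clock and 0.42 for glucocorticoid-induced genes, against 0.37 and 0.40, and Fkbp5 lost its call, as did Klf15 and Fkbp5 when any of several single arrays was left out, while the 2 other Fkbp5 probes gave 1.45 and 1.27 (adjusted p = 2.05e-07 and 2.72e-05); without wild-type saline 8 h replicate 39 the count was 284.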

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

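Tests of the explanations for the 3 patterns weighed here were chosen only after the results were seen, and the counts over other splits of the arrays were chosen before. The percentage of spots well above background on wild-type saline 4 h replicate 34 was 81.1%, apart from its group by 0.854 of the range. It was 1 of 54 tests of this kind, of which chance marks about 1 in 20. Probes without a gene name entered no comparison of genes, and of 11371 such probes kept, 3607 were called for dexamethasone in wild type at 4 h and 130 between genotypes under dexamethasone at 8 h.

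The response to dexamethasone differed between genotypes in 2605 genes at 4 h, 1002 at 8 h and 4538 in the mean, by a test of the difference itself. At 4 h the differences in log2 response were Nr3c1 0.48, Peli1 0.71, Tm9sf1 0.57, Zfp131 0.68, Tbcc 0.43 and Tbc1d23 0.71. Others were Fah -0.72, Kdm1a 0.74, Klf6 0.67, Csgalnact2 0.74 and Cbx2 -0.84. With the bright-to-dim covariate all of these except Fah lost their call, as did Fkbp5 and Cbs in the mean and none at 8 h. At 4 h Nr3c1, Tm9sf1 and Tbc1d23 were at -0.97 (called), -0.36 and -0.33 by their dimmest probes. At 8 h the differences were Nfe2l1 0.59, Bckdhb -0.59, Fah -0.79, Farp1 0.53 and Slc38a4 1.34. Others were Syt12 1.26, Mdh2 0.66, Ssr3 0.56, Fasn 0.87 and Mtmr1 0.71. In the mean they were Prodh -0.45, Fkbp5 1.25, Fah -0.75, Tm9sf1 0.51, Tbcc 0.40, Nfe2l1 0.46 and Farp1 0.43. Others were Mtmr1 0.65, Mdh2 0.61, Cbx2 -0.77, Pkig 0.51, Rpp21 0.51, Bckdhb -0.35 and Cbs -1.19. The Fkbp5 call in the mean ended in 30 alternatives, 21 of them leaving out 1 array, and its 2 other probes gave -0.065 and 0.043.

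The dexamethasone effect differed between 8 and 4 h in 923 genes in wild type and 463 in the knockout, again by a test of the difference. In wild type the differences were Klf15 -1.14, Nr3c1 0.56, Fkbp5 -3.09, Tsc22d3 -1.08, Per1 -0.91, Mt2 -1.09, Aass -0.64, Fat3 -2.33 and Sh3rf2 2.08. Others were Fam160a1 -1.32, Fam107a -2.26, Mcf2l -1.30, Slc25a33 -1.53, Zbtb8b -2.87, Fam117b -1.37, Afap1l2 1.54 and Coro2a -1.28. In the knockout they were Fkbp5 -2.91, Tsc22d3 -1.13, Per1 -1.05, Aass -0.53, Fat3 -2.00, Mcf2l -1.20 and Sh3rf2 1.48. Others were Fam117b -1.18, Fam107a -1.82, Fas -1.15, Pcdh20 -1.56, Fzd2 1.35, Cdh11 -1.19 and Rab11fip1 0.93.

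On the 7 knockout saline arrays the bright probe of a gene was lower against its dim probe than on the other arrays, by a mean log2 ratio of -0.278. The difference was -0.191 after quantile normalization (exact permutation p = 8.33e-06), which argues against intensity-dependent scaling as the whole cause, and it had the same direction on 6 of 6 slides, which argues against slide differences. RNA quality or preparation of the knockout saline samples could give the -0.278, but cannot be told apart from genotype and treatment here, because probe positions were not used. The only 2 arrays marked for evaluation by the scanner software were among these 7 (4 h replicate 44, 8 h replicate 45). A biological difference of the knockout under saline is open and untested.

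Interaction calls were mostly higher in the knockout, 77.17% of those in the mean, against 65.6% with slide as a fixed block and 64.7% with quantile normalization, which argues against slide differences and scaling alone as the whole cause. The deposited table, which also takes another signal, gave 57.62%, and at 8 h quantile normalization left 47.76%, so scaling is a candidate explanation of part. Among genes called in the mean interaction, the dimmest probe moved the same way in 47.4%, so the probe-level difference of the knockout saline arrays is a candidate explanation of part of the calls. Whether it is the whole cause stays open: with the ratio of bright to dim probe as a covariate 480 genes passed (84.79% higher), of which 222 were among the 4538, and at 4 h 3 passed. A difference in response between genotypes, which the design names, remains open.

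Of 146 genes within 10 Mb of Klf15, 4 differed at least 2-fold between genotypes in the mean, against 26 of 15203 elsewhere (Fisher's exact test, p = 0.000178). The 2-fold limit was chosen after the differences were seen, over all called neighbours p was 0.344, and 1 of the 4, Vmn1r53, lost its call with the bright-to-dim covariate, so chance placement stays open. Flanking DNA of another strain around the targeted gene might give the 4 genes, and stays open because strain sequence was not used here, as does an effect of Klf15 itself.

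Other splits of the same arrays were counted, the real one included. For dexamethasone in wild type at 4 h, 1 of 35 splits called as many genes (5629, highest other 823). In the knockout it was 1 of 35 at 4 h (6550, highest other 4913) and 1 of 35 at 8 h (6608, 1435). Between genotypes it was 1 of 35 in each case, under saline at 4 h (3842, 2709) and 8 h (2117, 464) and under dexamethasone at 4 h (149, 33) and 8 h (760, 287), and 1 of 100 in the mean (2982, 438). Of 100 splits, the mean interaction gave 1 (4538, 4) and the time difference in the knockout 1 (463, 323). Saline at 8 against 4 h gave 1 (500, 28). The interaction gave 3 at 4 h (2605, 2694) and 3 at 8 h (1002, 1345). The time difference in wild type gave 2 (923, 2109). In interactions and time differences the share decides nothing. Splits also remove the genotype or time effect, and those above the real count can carry it. In the other effects the share was the lowest possible. As arrays of a slide correlated (0.41), it leaves chance and slide differences open. For dexamethasone in wild type at 8 h the 10 splits are too few for a share under 0.05 (real 3625, highest other 2).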

How the results depend on the processing

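Alternatives chosen only after the data were seen are normexp on the median signal, median scaling, the 2 covariates, the dimmest probe, and the fits without slide 8 or without arrays marked for evaluation; normexp on the mean signal was not run, because that signal is not in the files used here. Of 370 gene results, 345 were called, of which 224 kept their call in every alternative and 121 lost it in at least 1, and 11 of the 25 others gained one. Of 450 list results, 116 were called, of which 69 kept their call everywhere, and 80 of the 334 others gained one. Results that kept their direction lost their call most often with the dimmest probe (43, beside 16 results that changed sign), the bright-to-dim ratio as a covariate (36), only the groups compared (29), the deposited table (27) and normexp (27), against 21 with the mean of a gene's probes (beside 6 that changed sign), 16 with quantile normalization and 3 with array weights. With only the groups compared, calls outside the genotype effect under dexamethasone ended for Tsc22d3, Acadsb and Tnni2 (dexamethasone, wild type, 8 h), Nr3c1 (knockout, 4 h and 8 h), Mt2 (genotype, saline 4 h), Clec4f, Pecam1 and Tie1 (saline 8 h), Per1 and Aass (time difference, wild type and knockout), and Klf15, Fkbp5 and Per1 (saline time effect). The counts for dexamethasone in wild type at 4 h and in the knockout at 4 h and 8 h stayed within 1.5 times of the reported ones in all alternatives. Signal over background limits the dimmest genes, for which only bounds were given. The cause of a change was not tested, except that some alternatives use fewer arrays by construction.

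Counts of called genes moved by more than 1.5 times as follows. For the genotype effect under saline at 4 h (3842) they were 2333 with quantile normalization, 1727 with normexp, 1581 in the deposited table, 6072 with array weights, 2160 with the share of probes above background as a covariate and 21 with the bright-to-dim ratio as one. At 8 h (2117) they were 1073 with normexp, 1165 in the deposited table, 336 with only the groups compared, 6274 with array weights, 4073 and 4027 with slide as a fixed and a random block, and 1383 without arrays marked for evaluation. Under dexamethasone at 4 h (149) they were 75 with only the groups compared, 296 with slide as a random block and 93 without slide 8, and at 8 h (760) 50 with only the groups compared, 1777 with array weights and 414 with slide as a fixed block. The mean genotype effect (2982) gave 5232 and 5047 with slide as a fixed and a random block and 1180 with the bright-to-dim covariate. The interaction at 4 h (2605) gave 1138 with quantile normalization, 649 with normexp, 530 in the deposited table, 1395 with only the groups compared, 1605 and 1578 with the mean and the dimmest of a gene's probes, 881 without slide 8 and 3 with the bright-to-dim covariate. At 8 h (1002) it gave 379, 160 and 186 with the first 3 of these, 573 with only the groups compared, 642 and 664 with the mean and the dimmest probe, 3303 with array weights, 445 with slide as a fixed block, 1627 with the share covariate and 293 with the bright-to-dim covariate. The mean interaction (4538) gave 2949, 2270 and 2251 with quantile normalization, normexp and the deposited table and 480 with the bright-to-dim covariate. Dexamethasone in wild type at 8 h (3625) gave 1538 with only the groups compared. The time difference in wild type (923) gave 606 with only the groups compared, 1655 with array weights, and 1504 and 1725 with slide as a fixed and a random block. In the knockout (463) it gave 294, 1815 and, with the random block, 887. Saline at 8 against 4 h (500) gave 2147 with array weights, 878 and 1044 with slide as a fixed and a random block, and 292 without arrays marked for evaluation.

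Leaving out each array in turn gave 2158 (without knockout saline 4 h replicate 43) to 3976 for the genotype effect under saline at 4 h, 919 (without wild-type saline 8 h replicate 39) to 2149 at 8 h, 92 (without wild-type dexamethasone 4 h replicate 51) to 144 under dexamethasone at 4 h, and 303 (without wild-type dexamethasone 8 h replicate 55) to 1160 (without knockout dexamethasone 8 h replicate 62) at 8 h. The interaction gave 1310 (without knockout saline 4 h replicate 43) to 3237 at 4 h and 356 (without wild-type dexamethasone 8 h replicate 55) to 1225 at 8 h. The time difference gave 605 (without wild-type dexamethasone 8 h replicate 55) to 1101 in wild type and 277 (without knockout saline 4 h replicate 41) to 469 in the knockout, and the saline time effect 284 (without wild-type saline 8 h replicate 39) to 508.

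Signs turned with the choice of probe. With the dimmest probe, Kcnt1 was at -0.53 and Kcnab1 at -0.36 for dexamethasone in wild type at 4 h, Kcnt1 at -0.072, Fosl2 at -0.26 and Fkbp5 at 1.74 at 8 h, and Ivd at -0.10 in the knockout at 8 h. Fntb was at -0.026 and Adcyap1r1 at -0.81 in the genotype effect under saline at 8 h, Tm9sf1 at -0.36 and Tbc1d23 at -0.33 in the interaction at 4 h, and Tm9sf1 at -0.32 in the mean interaction. Nr3c1 was at 0.27 and 0.82 with the mean and the dimmest of its probes in the genotype effect under saline at 4 h, 0.33 and 0.98 at 8 h, 0.091 and 0.35 in the mean genotype effect, -0.31 and -0.97 in the interaction at 4 h and -0.42 and -1.11 in the mean interaction. Fkbp5 was at 1.21 with the mean of its probes for dexamethasone in wild type at 8 h. With slide as a fixed block, Rgmb was at -0.13 in the genotype effect under saline at 4 h.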
